A study of Arabidopsis thaliana with 6 samples.

How the data were processed

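RNA was extracted from Arabidopsis seedlings with TRIzol, and libraries were made from total RNA with the NEBNext Ultra kit for Illumina, per the labels. How transcripts were selected is not given in the sources used here. The series holds 6 libraries, 3 from wild-type seedlings that received water and 3 from wild-type seedlings that received CLE9 peptide at 200 nM. Seedlings were 7 days old. The labels do not say whether the libraries of a group came from separate cultures of plants, so p-values measure only the spread between these libraries, which may be technical.

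The deposited table gives FPKM (fragments per kilobase of transcript per M mapped fragments, M being 1e6) for 27416 genes in each library, per the file headers. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the genome build TAIR10, without a role or an order for any of them. Which tool gave the FPKM, and whether counting used the strand, is not given in the sources used here. Reads of genes that lie at the same position, of antisense partners and of near-identical copies can therefore have been divided between them in the authors' counting. In the table, 85 genes share their position with another gene. Coordinates are those of the deposited table (TAIR10) and count from 1. A RefSeq annotation of build TAIR10.1 was used for symbols, product names and InterPro protein domains only, since 34.0% of the matched genes had the same start in both. Of the 27416 genes, 26719 matched an entry there by locus identifier, 10376 had a symbol and 21760 had a domain. A gene without a symbol is given by its locus identifier.

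The table holds no counts, so depth was estimated from the low values. In single-exon genes the product of FPKM and gene length piles up at the value of 1 fragment, and 4915 such genes gave estimates between 19.9 and 30.7 M fragments per library. Between 34.2% and 41.6% of the low values were whole within 0.1 fragments, against 20% by chance, so the estimates are approximate and reads could not be recovered. At these depths 1 fragment in a transcript of 1 kb is worth between 0.0326 and 0.0504 FPKM.

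All values were analysed as log2(FPKM + 1). A pseudocount of 1 understates the change of genes near or below 1 FPKM. Genes with a mean of 1 FPKM or more over the 6 libraries (17812 genes) were tested with limma 3.58.1 in R 4.3.3 (linear model with group only, empirical Bayes moderation with a mean-variance trend). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called, with no minimum change. Fold changes are CLE9 minus control on the log2(FPKM + 1) scale with their standard error.

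Gene lists were tested on the same fit with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 28 lists of 5 or more tested genes. The lists held 450 genes in all, none in more than 1 list, of which 373 were tested. They cover CLE signalling, xylem differentiation, the stomatal lineage, guard cells, 8 hormone or immunity responses, abiotic stress and nutrient responses, secondary metabolism, cell wall loosening, the cell cycle, photosynthesis, root tissue markers, the circadian clock, touch and wounding, and sugar starvation. Camera with an estimated correlation and fry were run beside the preset one. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise.

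The rule for named genes took the 12 largest increases and decreases among called genes whose groups did not overlap. Where fewer than 5 genes passed in a direction it took the 10 smallest p-values in that direction, whatever their threshold, and this was the case in both directions. It also took CLE9, CLE10, CLV1, BAM1, BAM2, BAM3 and HSL1, and the 4 members with the smallest p of each called list. After the data were seen, up to 12 genes per direction with the largest change among calls of the blocked fit were added, provided they changed the same way in all 3 pairs.

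The replicate numbers in the labels are shared by both groups. Whether they pair the libraries was checked on the deviations from the group means before the fits were compared. Control and CLE9 libraries of the same number correlated at 0.545, 0.743 and 0.583 across genes for replicates 1, 2 and 3. All are over 0.1, so the numbers were taken to pair the libraries. Control replicate 1 correlated more with CLE9 replicate 3 (0.664) than with CLE9 replicate 1, and control replicate 3 more with CLE9 replicate 1 (0.620) than with CLE9 replicate 3. The values thus favour the pairs of the labels for neither replicate 1 nor replicate 3, and the pairing rests largely on replicate 2. Values from a fit with the replicate number as a block are given where they change a call.

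Each step was tested on simulated libraries drawn from the means, replicate effects and residual spread of the 17812 genes. With the libraries' own replicate effects, the group-only test recovered 0% of genes given a log2 change of 1 and 26% of those given a change of 2. The blocked test recovered 0% and 37%, and neither called an unchanged gene. Without replicate effects the group-only test recovered 46% and 73% and the blocked test 1% and 36%, so the block costs power where replicates do not differ, and each called 1 unchanged gene. A list shifted by design was called by camera, and 0 of the other lists were. Residual noise was drawn independently for each gene, so this cannot show false list calls that come from correlated genes. In the real libraries the estimated correlation was 0.77 for the immunity list and 0.97 for the photosynthesis list.

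Alternatives were pseudocounts of 0.1, 0.01 and 5, no filter and a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, limma without the trend, with robust moderation and with array weights, stricter thresholds, organellar genes left out, the replicate block, and each library left out in turn. Leaving out both replicate 2 libraries, summing genes of 1 position, combining the block with the other alternatives and testing families of InterPro domains of 10 to 300 tested genes were chosen after the data were seen. The setting with organellar genes left out also rescaled each library to the same summed FPKM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.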

Results

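RNA abundance was measured in wild-type Arabidopsis thaliana seedlings, in 3 control libraries (water) and 3 libraries of seedlings given 200 nM CLE9. CLE9 is a small secreted peptide of the CLAVATA3/EMBRYO SURROUNDING REGION-related family, whose members are perceived by leucine-rich repeat receptor kinases. The duration of the treatment is not given in the sources used here. The estimated depth was 28.02, 23.2 and 30.7 M fragments in control replicates 1, 2 and 3, and 26.9, 19.9 and 22.2 M in CLE9 replicates 1, 2 and 3. Between 16575 and 17874 genes per library had 1 FPKM or more.

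Replicate 2 of both groups stood apart from the other 4 libraries. The first principal component held 71.0% of the variance and placed control replicate 2 and CLE9 replicate 2 away from the rest. The second (15.4%) placed CLE9 replicates 1 and 3 away from the controls. On the first component each CLE9 library also scored above the control of its number. The scores were -15.6 against -63.5, 115.6 against 45.1 and -17.2 against -64.4 for replicates 1, 2 and 3. The difference between the groups thus lay partly along the same axis as the departure of replicate 2. Across genes, control replicates 1 and 3 correlated at r = 0.991 and CLE9 replicates 1 and 3 at r = 0.977. Control replicate 2 correlated at 0.879 with control replicate 1, and CLE9 replicate 2 at 0.840 with CLE9 replicate 1. Genes induced by touch and wounding had a median 3.63 log2 units higher in control replicate 2 than the mean of the other controls, and 3.07 higher in CLE9 replicate 2 than the mean of the other CLE9 libraries. Other lists shifted in both as well, among them jasmonate (2.31 and 1.57) and ethylene (2.14 and 1.15) upward. The cell cycle (-0.77 and -1.08) and root tissue marker lists (-1.39 and -2.53) shifted downward.

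**Figure D1:**
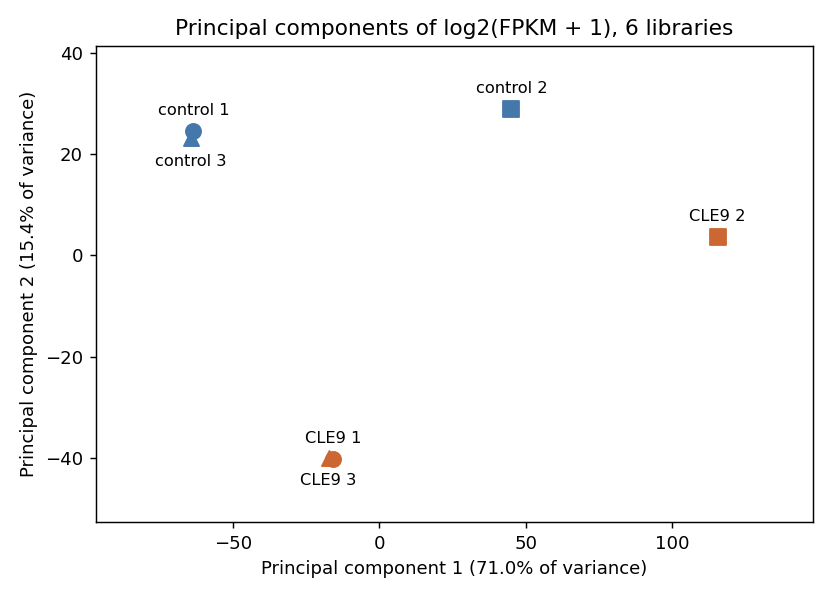
Principal components 1 (x axis) and 2 (y axis) of log2(FPKM + 1), in units of component score, with 1 point per library, colour for the group and shape for the replicate number. Replicate 2 of both groups lies to the right along component 1 (71.0% of the variance), and CLE9 replicates 1 and 3 lie below the other libraries along component 2 (15.4%). Each CLE9 library also lies to the right of the control of its number along component 1.

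The comparison of CLE9 with water asked which transcripts differ in seedlings exposed to the peptide. Genes of the early immune response to microbial patterns were higher in the CLE9 libraries, and the list of 17 such genes rose as a set (mean log2 change 2.18, camera adjusted p = 1.8e-08). This call did not hold with an estimated correlation (adjusted p = 0.928, and 0.780 with the block). All 17 were higher with CLE9 in each of the 3 pairs of libraries with the same replicate number. WRKY30, a transcription factor gene of the WRKY family, was at 5.07 ± 7.98 FPKM in controls and 129.9 ± 67.1 FPKM with CLE9 (SD, n = 3 each), a log2 change of 5.18 ± 1.03 (SE). PROPEP2 and PROPEP1, which encode precursors of the damage signal peptides perceived by PEP receptors, differed by 3.06 ± 1.02 and 1.098 ± 0.32. PAD3, the last enzyme of camalexin synthesis, was at 0.379 ± 0.117 and 2.202 ± 0.669 FPKM.

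Over all genes tested, 0 of the 17 immunity genes passed the group-only test, and 2 (PAD3 and WRKY30) rose when adjusted over the list alone. With the replicate block, 5 rose over all genes, and all 17 rose when adjusted over the list alone. The 5 were WRKY53, PROPEP2, PROPEP3, NHL10 and the NADPH oxidase gene RBOHD, named after their values were seen. The same genes were high in control replicate 2, where all 17 were above both other controls, with a median 3.104 log2 units above their mean, beside the 3.63 of the touch and wounding list. Without both replicate 2 libraries the list's mean change was 2.59 (adjusted p = 3.3e-18, and adjusted p = 0.288 with an estimated correlation) and 16 of its genes rose, in a comparison of 2 libraries with 2 chosen after the data were seen.

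**Figure D2:**
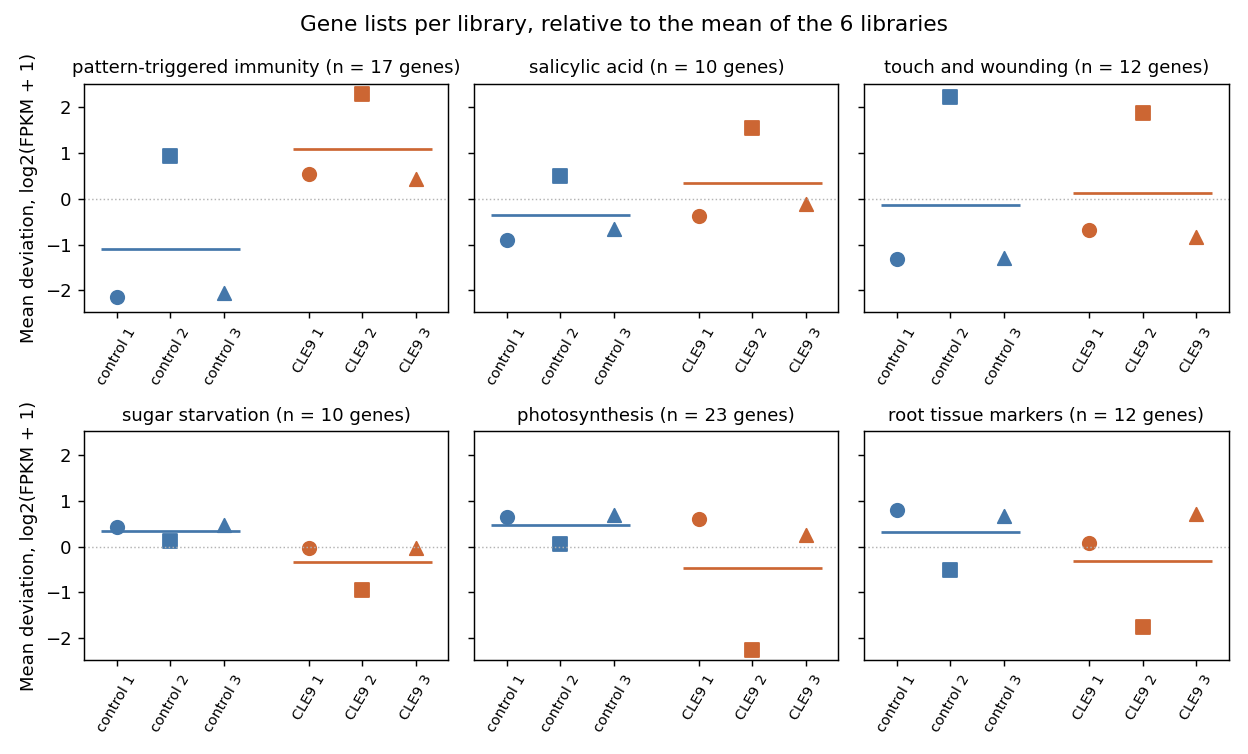
Mean deviation of 6 gene lists (y axis, log2(FPKM + 1) relative to each gene's mean over the 6 libraries) in each library (x axis), with colour for the group, shape for the replicate number and a horizontal line at the group mean. The immunity list is lower in control replicates 1 and 3 (-2.14 and -2.07) than in CLE9 replicates 1 and 3 (0.55 and 0.43), but control replicate 2 (0.93) lies above both of these and below CLE9 replicate 2 (2.29). The touch and wounding list is highest in replicate 2 of both groups (2.21 and 1.89).

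Among single genes, limma called 1 of 17812 genes with group only (0 higher, 1 lower with CLE9), while 1586 had an unadjusted p under 0.05, 1039 of them higher and 547 lower. With the replicate number as a block, 355 genes changed, 311 higher and 44 lower, and all 355 moved the same way in the 3 pairs. A blocked call on 3 pair differences nearly requires the same sign in each, so this is no separate support. Leaving out both replicate 2 libraries gave 2024 calls (1498 higher, 526 lower), and 351 of the 355 were among them with the same sign. The remaining libraries are among those that gave the 355, so this overlap is no separate support either. In 206 of the 355 the groups did not overlap. Over all genes tested, the groups did not overlap for 2846 (16.0%, against 10% by chance if all 6 libraries were exchangeable). The same sign in all 3 pairs was seen for 8167 (45.9%, against 25% by chance if the pairs were independent). Replicates 1 and 3 were much alike (r = 0.991 in controls and 0.977 with CLE9). Neither condition can therefore be taken to hold, and no excess over chance can be read from these shares.

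The 1 gene called with group only, AT5G49448 (chromosome 5, 20051829 to 20052735), was at 42.9, 31.6 and 49.2 FPKM in controls and was listed at 0, 0 and 0.00166 FPKM with CLE9 (adjusted p = 0.00258). It shares this position with bZIP1, a transcription factor gene of the response to low energy, which was at 48.8, 37.3 and 52.1 FPKM in controls and at 128.8, 16.9 and 82.2 FPKM with CLE9. The sum of both genes was 87.3 ± 16.6 FPKM in controls and 76.0 ± 56.2 FPKM with CLE9 (SD, n = 3), so the value of either gene alone is uncertain. With genes of 1 position summed, 0 genes were called by limma and 1588 had an unadjusted p under 0.05.

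By the rule for named genes, the 10 smallest p-values in each direction were taken whatever the threshold. All 20 genes had groups that did not overlap, and all 20 were called with the replicate block. Both follow largely from the choice by smallest p on the same libraries, so they are no separate support. CNGC10, a cyclic nucleotide gated ion channel (chromosome 1, 132328 to 135831), rose from 3.67 ± 0.688 to 28.5 ± 3.91 FPKM (log2 change 2.66 ± 0.19, adjusted p = 0.0527 with group only and 0.0338 with the block). CRCK1, a calmodulin-binding receptor-like cytoplasmic kinase (chromosome 5, 23798562 to 23800823), rose from 2.89 ± 0.668 to 16.2 ± 0.701 FPKM (adjusted p = 0.0687 and 0.0338). The flavin-dependent oxidoreductase gene CTF2B rose by 2.86 ± 0.31 and the C1 domain gene AT5G40590 by 3.43 ± 0.39. The leucine-rich repeat kinase gene AT5G01950 rose by 1.73 ± 0.20 and AT5G15870, a glycosyl hydrolase of family 81, by 2.52 ± 0.31. The other 4 (AT3G50190, AT3G57630, AT5G39970 and AT4G24970) had log2 changes between 1.17 and 1.66.

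Of the genes that fell with the block, AT3G62550 (chromosome 3, 23135984 to 23137173), of the adenine nucleotide alpha hydrolase family, went from 103 ± 16.5 to 13.7 ± 2.23 FPKM, a log2 change of -2.83 ± 0.21 (adjusted p = 0.0527 with group only and 0.0338 with the block). PEPC1, listed as a phosphatase-related gene, went from 3.63 ± 0.261 to 0.895 ± 0.1798 FPKM. RAP2.10, an AP2/ERF transcription factor gene, had a log2 change of -1.51 ± 0.21, the phloem protein gene PP2-A14 one of -1.04 ± 0.15 and the homeobox gene HB-7 one of -1.08 ± 0.18. The other 4 (AT1G78995, AT5G25240, AT1G07280 and AT4G23870) lay between -1.59 and -1.12.

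**Figure D3:**
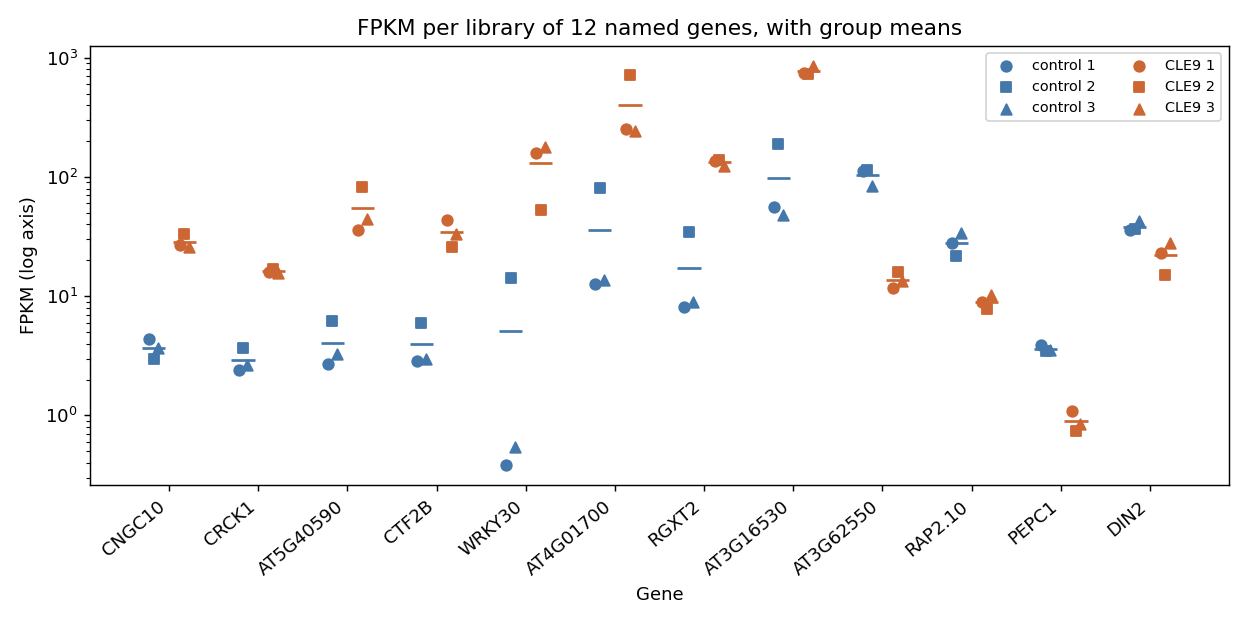
FPKM of 12 named genes (x axis) in each library on a log axis (y axis), with colour for the group, shape for the replicate number and a horizontal line at the group mean. The 8 genes on the left are higher in all 3 CLE9 libraries than in all 3 controls (CNGC10 28.5 against 3.67 FPKM), and the 4 on the right are lower (AT3G62550 13.7 against 103 FPKM).

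The largest increases among the blocked calls, a choice made after the data were seen, included the berberine-type oxidase genes AT1G26380 (log2 change 4.24 ± 0.44, SE with the block) and AT1G26420 (3.22 ± 0.42), and AACT1, an acyltransferase (3.99 ± 0.50). The chitinase genes AT4G01700 and AT1G02360 went from 36.0 ± 39.5 to 402 ± 270.1 FPKM and from 19.3 ± 15.5 to 150.9 ± 66.4 FPKM. The lectin gene AT3G16530 rose from 98.0 ± 79.8 to 777 ± 67.2 FPKM and the xylosyltransferase gene RGXT2 from 17.3 ± 15.0 to 133 ± 7.35 FPKM. XBAT34 (3.56 ± 0.52), PROPEP3 (3.38 ± 0.14), AT1G51920 (3.14 ± 0.41) and CYP83B1, an enzyme of indole glucosinolate synthesis (3.13 ± 0.40), were also among the 12. The decreases included AT1G52342 (-2.30 ± 0.31), MYB59 (-1.64 ± 0.23), the aquaporin gene PIP2;4 (-1.43 ± 0.19) and ZFHD1 (-1.40 ± 0.20). AT3G11110, AT1G78450, AT4G10910 and AT3G18320 lay between -1.48 and -1.34. MYB59 was not called without both replicate 2 libraries (adjusted p = 0.119). The groups overlapped for PROPEP3 and for all decreases named in this paragraph except AT1G52342. PROPEP3 was at 0.411, 27.3 and 0.356 FPKM in controls and 14.1, 263 and 14.3 FPKM with CLE9 (limma adjusted p = 0.632 with group only). For those decreases the limma adjusted p with group only lay between 0.586 and 0.759.

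Of the 311 genes higher with the block, 291 were also higher in control replicate 2 than in control replicates 1 and 3. The blocked count was 0 without pair 1 or without pair 3 and 1870 without pair 2, and it was 2 with a pseudocount of 0.1 and 3 without a filter on low values. The group-only count was 204 without control replicate 2, 4884 with array weights, and 0 without control replicate 1, CLE9 replicate 1 or CLE9 replicate 3.

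Lists that fell were those of sugar starvation and photosynthesis. The 10 genes induced by darkness and low sugar fell as a set (mean log2 change -0.69, camera adjusted p = 5.5e-04), and all 10 were lower in each of the 3 pairs. The call held with the block (adjusted p = 0.00293) but not with an estimated correlation (adjusted p = 0.928). ASN1, which encodes an asparagine synthase, was at 865 ± 68.8 FPKM in controls and 534 ± 116 FPKM with CLE9. The beta-glucosidase gene DIN2 was at 38.3 ± 3.502 and 22.1 ± 6.599 FPKM, MCCA of leucine breakdown at 228 ± 23.8 and 160.1 ± 4.82 FPKM, and the trehalose phosphate synthase gene TPS10 at 39.98 ± 10.5 and 24.8 ± 4.34 FPKM. Over all genes 0 of the 10 passed with group only or with the block, while 0 and 3 fell when adjusted over the list alone. The mean change was -0.38 without CLE9 replicate 2.

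The 23 nuclear photosynthesis genes fell as a set (mean log2 change -0.93, adjusted p = 0.00489), and this rested on CLE9 replicate 2. The call was lost with an estimated correlation (adjusted p = 0.928). The median change was 0.02 in pair 1, -2.33 in pair 2 and -0.45 in pair 3. Without CLE9 replicate 2 the mean was -0.04 (adjusted p = 0.429), and without both replicate 2 libraries it was -0.24 (adjusted p = 0.0534). The call was also lost under quantile normalization (adjusted p = 0.0752). No member passed over all genes or adjusted over the list alone (0 of 23). PSBO2 of photosystem II was at 1146 ± 237 and 647 ± 464 FPKM, PSBP-1 at 2569.7 ± 332 and 1609.6 ± 886 FPKM, the antenna gene LHCB6 at 1335 ± 485 and 814 ± 614 FPKM, and LHCB2.2 at 2263 ± 931 and 1296 ± 1085 FPKM. The LHCB1 and LHCB2 genes and the small Rubisco subunit genes have near-identical copies, so their single values are uncertain. Root tissue markers were lower in the same library, with a median 2.53 log2 units below the other CLE9 libraries. They were also lower in control replicate 2 (median shift of -1.39 against the other controls).

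Another 5 lists were called only with the replicate block. The salicylic acid synthesis and response list was called up (10 tested, mean log2 change 0.71, adjusted p = 0.0705 with group only and 0.00525 with the block). The ethylene list (15 tested, 0.45, 0.154 and 0.0184) and the heat shock list (10 tested, 0.65, 0.0574 and 0.0477) were also called up. The flavonoid and anthocyanin list was called down (5 tested, -0.55, 0.154 and 0.0298), as was the gibberellin and brassinosteroid list (10 tested, -0.46, 0.173 and 0.0400). The ethylene list was not alike in the pairs, with medians of 0.86, -0.30 and 0.41 in pairs 1, 2 and 3 and 5 of 15 genes higher in all 3. Medians in the pairs were 0.45, 1.1995 and 0.66 for salicylic acid (7 of 10 higher in all 3), 1.21, 0.295 and 0.32 for heat shock (6 of 10), -0.62, -1.002 and -0.399 for flavonoids (3 of 5 lower) and -0.83, -0.298 and -0.64 for gibberellin and brassinosteroid (5 of 10 lower). None held with an estimated correlation (adjusted p between 0.780 and 0.919 with the block). In the salicylic acid list 1 gene rose over all genes with the block, the transporter gene EDS5, and 3 rose when adjusted over the list alone. In the other 4 lists 0 passed over all genes. Adjusted over the list alone, 1 ethylene gene rose, 6 heat shock genes rose and 2 fell, 2 flavonoid genes fell, and in the gibberellin and brassinosteroid list 5 fell and 1, the gibberellin receptor gene GID1B, rose. Without both replicate 2 libraries the salicylic acid, ethylene, and gibberellin and brassinosteroid lists passed (adjusted p = 0.0133, 8.7e-05 and 0.0107), and the heat shock and flavonoid lists did not (0.0534 each). With an estimated correlation these 3 did not pass there (adjusted p = 0.653, 0.573 and 0.573). These means depend on single libraries. With group only, the salicylic acid list was called without control replicate 2, CLE9 replicate 1 or CLE9 replicate 3, the ethylene and heat shock lists without control replicate 2 or CLE9 replicate 3, and the gibberellin and brassinosteroid list without CLE9 replicate 2. Without CLE9 replicate 2 they were 0.115 for salicylic acid, -0.0023 for ethylene, 0.36 for heat shock and -0.037 for flavonoids, and without control replicate 2 they were 1.14, 1.21, 1.21 and -0.99. The salicylic acid mean was also 0.44 without control replicate 1 and 1.07 without CLE9 replicate 1, and the ethylene mean 0.041 and 0.087 without control replicates 1 and 3 and 0.71 without CLE9 replicate 3. Heat shock was at 0.35 and 0.405 without control replicates 1 and 3 and 0.99 without CLE9 replicate 3, and flavonoids at -0.33 and -0.32 without control replicates 1 and 3. The touch and wounding list had a mean change of 0.25 between the groups (adjusted p = 0.715), a value that turns with single libraries. It was -0.34, 1.42 and -0.33 without control replicates 1, 2 and 3, and 0.65, -0.62 and 0.73 without CLE9 replicates 1, 2 and 3. Of these 6, only that without control replicate 2 was called (adjusted p = 0.00469), and the mean was 0.55 without both replicate 2 libraries (adjusted p = 0.0534).

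The genes of the peptide and its receptors were not called with either fit. CLE9 was at 1.64 ± 0.272 FPKM in controls and 1.75 ± 0.814 FPKM with CLE9 (log2 change 0.03 ± 0.25, adjusted p = 0.985), and CLE10 had a change of 0.26 ± 0.22. The receptor kinase genes CLV1, BAM1, BAM2, BAM3 and HSL1 had changes of 0.22 ± 0.17, -0.39 ± 0.32, 0.01 ± 0.26, -0.15 ± 0.21 and -0.41 ± 0.20, with adjusted p-values of 0.643 or more. In the list of CLE signalling genes (20 tested, mean 0.07, median -0.05, adjusted p = 0.715, mean 0.0066 without control replicate 2 and 0.027 without CLE9 replicate 3) 1 gene rose with the block over all genes, and it rose with either fit when adjusted over the list alone. This was BAK1, a co-receptor of several receptor kinases, including those of immunity and brassinosteroids, named after its values were seen. BAK1 was at 23.0, 44.8 and 24.6 FPKM in controls and at 78.9, 95.7 and 79.2 FPKM with CLE9 (log2 change 1.49 ± 0.29, adjusted p = 0.255 with group only and 0.0435 with the block). The lists of xylem differentiation (11 tested, mean -0.35, adjusted p = 0.135), the stomatal lineage (16 tested, -0.09, 0.851) and guard cells (13 tested, 0.01, 0.851) were not called with either fit. The xylem mean was -0.096 without CLE9 replicate 2 and -0.71 without CLE9 replicate 3, where the list was called down (adjusted p = 7.7e-06). With 1 library left out the stomatal mean ran from -0.25 to 0.075 and the guard cell mean from -0.088 to 0.18, and neither list was called.

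The remaining lists were not called with either fit, with adjusted p-values between 0.204 and 0.950 with group only and between 0.05003 and 0.791 with the block. Mean log2 changes were -0.64 for root tissue markers (adjusted p = 0.337, and 0.05003 with the block), -0.37 for cold and dehydration, -0.34 for phosphate starvation, -0.18 for the cell cycle, -0.15 for abscisic acid response, -0.14 for auxin, -0.13 for cell wall loosening and -0.06 for the circadian clock. They were 0.58 for glucosinolates, 0.41 for oxidative stress, 0.36 for hypoxia, 0.35 for jasmonate, 0.19 for nitrate, 0.17 for cytokinin and below 0.01 for iron deficiency. The clock list holds morning and evening genes, so opposite changes can cancel in its mean. In pair 2, for example, CCA1 changed by -2.71 and ELF4 by 2.51. Several of these results turn on single libraries. Cold and dehydration was called down without control replicate 1 (mean -0.67, adjusted p = 0.0209), control replicate 3 (-0.77, 0.00728) or CLE9 replicate 2 (-0.57, 0.0478), and its mean was 0.31 without control replicate 2 and -0.203 without CLE9 replicate 3. Root tissue markers were called down without CLE9 replicate 3 (-1.15, 0.0384), and their mean was -0.39 without control replicate 1, -1.05 without control replicate 2 and 0.078 without CLE9 replicate 2. Phosphate starvation was called down without CLE9 replicate 2 (-0.404, 0.0176). Hypoxia was called down without CLE9 replicate 2 (-0.31) and jasmonate up without control replicate 2 (1.1605), against means of 0.36 and 0.35. Against the other libraries of its group, the hypoxia list had a median shift of 1.78 in CLE9 replicate 2 and -0.51 in control replicate 2. The other means also moved by over 1.5 times or changed sign, without a call. They ran from -0.45 to 0.199 for the cell cycle (without control replicate 2 and CLE9 replicate 2), -0.302 to 0.054 for auxin (CLE9 replicates 3 and 2), -0.295 to 0.088 for cell wall loosening (CLE9 replicates 2 and 1), -0.300 to 0.129 for abscisic acid (control replicates 3 and 2) and -0.243 to 0.056 for the clock (CLE9 replicate 2 and control replicate 2). They ran from 0.283 to 0.781 for glucosinolates (CLE9 replicates 2 and 1), 0.202 to 0.749 for oxidative stress (control replicates 1 and 2), 0.0904 to 0.311 for nitrate (CLE9 replicates 3 and 2), 0.0079 to 0.344 for cytokinin (control replicates 3 and 2) and -0.231 to 0.375 for iron deficiency (CLE9 replicates 3 and 2). The medians of the glucosinolate, cytokinin and iron deficiency lists were -0.01, -0.03 and -0.02, opposite in sign to their means, and camera gave the jasmonate list the direction down. Single members passed over all genes with the block, chosen for naming after their values were seen. In the glucosinolate list CYP83B1, of indole glucosinolate synthesis, and SUR1, of glucosinolate synthesis, rose (SUR1 by 1.60 ± 0.36). In the auxin list IAA3 fell (-1.002 ± 0.25). Adjusted over the list alone with the block, 5 genes rose and 3 fell in the glucosinolate list, 5 and 1 in jasmonate, 3 and 3 in touch and wounding, 3 and 1 in oxidative stress, and 1 and 4 in abscisic acid response. For cytokinin 2 rose, for the clock 1 rose, for auxin 1 fell, and in the other lists 0 passed. The phosphate starvation list (mean -0.50, adjusted p = 0.0107) and the jasmonate list (0.64, 0.0337) passed without both replicate 2 libraries, but not with an estimated correlation there (adjusted p = 0.573 and 0.653).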

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

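The block combined with other alternatives, leaving out both replicate 2 libraries or 1 pair, and summing genes of 1 position were chosen after the data were seen. The file holds FPKM only, so the planned count tests were not run, and robust moderation and a minimum change do not apply to camera. The cause was not tested for any of the differences below. The 1 gene called with group only became 4 with a pseudocount of 5, 3 with a filter at 5 FPKM, 2 under quantile normalization, 0 with genes of 1 position summed, 4884 with array weights (weights of 0.177 and 0.111 for replicate 2 of control and CLE9), 355 with the replicate block and 2024 without both replicate 2 libraries. It ranged from 0 to 204 with 1 library left out, 204 being without control replicate 2. The 355 blocked calls became 2 with pseudocounts of 0.1 and 0.01, 599 with 5, and 3 without a filter. They became 584 as TPM, 683 under median-of-ratios scaling, 744 under quantile normalization, 1439 with array weights and 3 at an adjusted p under 0.01. With organellar genes left out there were 625, but this setting also rescaled each library to the same summed FPKM. Chloroplast-encoded genes held at most 0.0596% of the summed FPKM (CLE9 replicate 1). The blocked calls became 0 without pair 1 or pair 3 and 1870 without pair 2.

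The 3 called lists became 5 without a filter, 6 with array weights, 8 with the replicate block (5 further lists), 7 without both replicate 2 libraries, and 0 with an estimated correlation or fry. With 1 library left out they ranged from 4 to 8. The 8 blocked lists became 4 with a filter at 5 FPKM, at an adjusted p under 0.01 and without pair 1, and 0 with an estimated correlation or fry. The immunity (mean 2.18) and sugar starvation (-0.69) lists kept their direction in all alternatives and their call in all except these last (adjusted p = 0.928 and 0.881). The photosynthesis list (-0.93) lost its call there too (0.928 and 0.948), under quantile normalization (mean -0.81), without both replicate 2 libraries (-0.24), and without 1 library between -1.46 and -0.042, lost at the latter, without CLE9 replicate 2. Against an uncalled main result, the hypoxia list was called down without CLE9 replicate 2 (-0.31, and up to 0.72 without another library). The jasmonate list, down by camera with a mean of 0.35, was called up without control replicate 2 (1.1605, the lowest mean being -0.17 without CLE9 replicate 2) and without both replicate 2 libraries (0.64). Beside the genes and the 5 further lists named above, the block changed no other call. Among named genes 1171 values kept their side of the threshold, 152 passed it and 3 lost it, and 0 reversed sign with a call in either fit. Uncalled genes that changed sign are counted as kept, such as BAM2 (0.01, and -0.20 without both replicate 2 libraries).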

Other observations

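The tests of protein domain families, clock genes, the touch and wounding list and root tissue markers, that of material of CLE9 replicate 2, that without CLE9 replicate 2, and the splits for blocked lists were chosen after the results were seen. The splits for the other counts, the test of material of CLE9 replicate 1 or 3 and that of library composition were set before.

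With the replicate block, camera at the preset correlation called 58 of 758 InterPro domain families up and 38 down, and with an estimated correlation it called 0 (adjusted p = 0.996 for the NB-ARC family). Many of these entries share genes, some of them members of the fixed lists, and the families below are a choice among them. The NB-ARC domain of intracellular immune receptors had a median log2 change of 0.40 over 122 genes, 78 of them higher in all 3 pairs and 7 lower (adjusted p = 2.8e-13). WRKY transcription factors (54 genes, median 0.79, 33 higher in all pairs), VQ proteins (26 genes, 0.95, 19), legume lectin domains (33 genes, 0.74, 20) and DUF26 domains, found in cysteine-rich receptor kinases (44 genes, 0.97, 28), were also called up. Aquaporins and their relatives (major intrinsic protein, 29 genes, median -0.53, 23 lower in all pairs) and xyloglucan endotransglucosylases (27 genes, -0.58, 13 lower) were called down, as were histone core domains (39 genes, -0.35, 19 lower). Direction was kept by all 96 families under TPM, median-of-ratios and quantile scaling, and 70 were also called without both replicate 2 libraries. Another split of the libraries called 108 families, so these calls do not stand out from it.

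Other splits of the libraries are too few for a share under 0.05. Of the 10 splits of the 6 libraries, 1 called as many genes as the real one (1, highest other 0) and 10 called as many lists (3, highest other 17). The 4 splits that kept both replicate 2 libraries together called 11 to 17 lists, which points to a structure of the libraries, and the real split called the fewest. Of the 4 splits that part all 3 pairs, with the block, 1 called as many genes (355, highest other 0), 4 called as many lists (8, highest other 13) and 2 called as many families (96, highest other 108). The other 3 exchange control and CLE9 within 1 pair. List and family calls at the preset correlation therefore do not stand out among the splits.

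Replicate 2 of both groups stood apart from the other 4 libraries. Mixing of material of CLE9 replicate 1 or 3 into control replicate 2 is argued against as the cause of most of its departure. Some mixing beside another cause is not excluded by this test. Of the 2893 genes that control replicate 2 moved by over 1 log2 unit, 69.2% lay more than 0.5 outside the range of the 4 libraries of pairs 1 and 3. Material of CLE9 replicate 2 in it may contribute, since 9.02% of these genes lay that far outside the range of control replicates 1 and 3 and CLE9 replicate 2, but a cause shared by both libraries would give this too. Harvest at another time of day may contribute, since evening minus morning clock genes shifted by 2.87 in control replicate 2 and 6.23 in CLE9 replicate 2. Handling or wounding before harvest may contribute too, since the touch and wounding list shifted by 3.63 and 3.07, above 100% of 10000 random lists matched on expression. The immunity, jasmonate, ethylene and clock lists also lay above 100% of such lists in both libraries. Random lists drew genes independently, so the percentile does not single out handling. Material of CLE9 replicate 2, time of day and handling all stay open, with no biological explanation tested.

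The pattern-triggered immunity list rose with CLE9, and a shift in library composition is argued against, as the median change of all tested genes was -0.055 and the list's median was 1.69 as deposited and 1.71 under quantile normalization. Handling or wounding of the CLE9 seedlings cannot be told apart from the peptide: in pairs 1 and 3 the touch and wounding list had a median rise of 0.42 against 2.05 for immunity, but its members ranged from -1.77 to 3.06. Control replicate 2 minus control replicate 1 correlated with CLE9 replicates 1 and 3 minus control replicate 3 at r = 0.571 (rho = 0.446) across 17812 genes. These contrasts share no library, but control replicates 1 and 3 correlated at r = 0.991, so both subtracted nearly the same baseline. That alone can give a positive r, and the genes are not independent. A response to the peptide remains a hypothesis beside the explanations left open here.

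The photosynthesis list fell with CLE9. CLE9 replicate 2 alone may account for it, as the mean change was -0.042 without that library. A smaller share of green tissue there would raise root tissue markers, but they shifted by -2.53 in it, with 11 of 12 lower. They also shifted by -1.39 in control replicate 2, so a fall shared by both replicate 2 libraries may mask a change in tissue share. The markers therefore gave no sign of a larger root share but cannot exclude one. Harvest of that library at another time of day may contribute, since its evening minus morning clock shift exceeded that of control replicate 2 by 3.36. An effect of CLE9 in that library stays open and was not tested apart from these.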
